A study of Mus musculus with 6 samples.

How the data were processed

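Gene expression was measured in endothelial-enriched RNA from carotid arteries of wild-type C57Bl/6J mice on Illumina bead arrays, on which biotin-labelled RNA binds beads that carry 1 probe sequence each. The sample descriptions place 3 arrays under stable flow and 3 under disturbed flow. The labels do not say whether the 3 samples of a group came from separate animals or from pools, so p-values measure only the spread between these samples, which may be technical. Total RNA was extracted with a phenol reagent, cleaned on columns with DNase treatment and checked on a Bioanalyzer, per the labels' protocols.

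The deposited table of unprocessed values holds 1 signal intensity per probe and array, with no background subtraction and no normalization between arrays, per the file headers and the values, none of which lay below 0. Beside each signal the deposited table gives a detection p-value, which compares the probe with negative control beads. GenomeStudio 2011.1 is named in the submitters' processing notes, and its settings are not given in the sources used here. The deposited series matrix holds a second set of intensity values made by the authors on a linear scale, not centred. All 6 matrix columns share a minimum of -17.0 and a maximum of 9720, and 36.0% to 36.5% of each column lay below 0, with column medians of 2.50 to 2.62. These values have the form of background-subtracted and quantile-normalized intensities, a step that no label states.

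The matrix columns and the sample descriptions disagree about the groups. Each of the 6 matrix columns had the same rank order over probes as 1 scanned array (rank correlation 1), and in 6 of 6 cases that array was described as belonging to the other group. Rank correlations with the column's own described array were 0.345 to 0.759. Arrays were grouped here by the descriptions, which name the scanned array, and every signed difference is the arrays described as disturbed flow minus the arrays described as stable flow. Under the names of the matrix columns each sign would be the opposite one, and neither source settles which is right.

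Signals were background-corrected, quantile-normalized and put on a log2 scale with neqc in limma 3.58.1 (R 4.3.3), which estimates the background from the detection p-values, with an offset of 16. Of 45281 probes, the 12546 with a detection p under 0.05 on at least 3 of the 6 arrays were tested. Groups were compared per probe with limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Gene names came from the platform annotation, updated through gene identifiers: 34885 probes had 1 symbol, 18 had several and were not named, and 10378 are unnamed here. The tested probes stand for 6980 genes, and the probe with the highest mean log2 intensity stands for its gene in the lists and the fixed set, while a gene named for its small p is given by the probe with that p. Probes were not placed on a genome build, so no coordinates are given.

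There were 32 gene lists fixed before the data were examined, and the 24 with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, two-sided, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The rule for named genes, also fixed before the data were examined, takes the 10 genes with the smallest p in each direction where fewer than 5 pass the threshold, at most 2 genes with the smallest p for a list without a passing gene, and a fixed set of flow, matrix and vessel wall genes. From these the text names the fixed set, the first 5 by p in each direction, and the examples of 6 lists, a selection made after the values were seen. Of the fixed set, Thbs2, Tgfb1 and Ptprc had no probe that passed the filter, and 1 gene is not reported here.

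All 3 arrays described as stable flow lay on 1 slide and all 3 described as disturbed flow on the other, so slide and group cannot be told apart and no slide term could be fitted. The number of arrays limits the precision: the median standard error of a log2 difference was 0.45. Arrays were also uneven before normalization. The interquartile range of log2 signal over the tested probes was 0.14 on stable flow replicate 2 and 0.30 to 0.93 on the others. The array weight of stable flow replicate 2 was 0.28, against 0.67 to 2.10 for the others. The fit was tested on simulated data with 200 changed probes among 12546 and 20 runs. Simulated errors were normal and independent between probes, with the variances that limma had already moderated, scaled for each array. The fit recovered 0.7% of planted log2 changes of 1, 26.1% of changes of 2, 78.2% of changes of 3 and 92.4% of changes of 4. Recovery in the measured data may be lower, since their errors need not follow this model. Camera called a list of simulated independent genes shifted by 1 in 20 of 20 runs and called 2 of 460 other lists. Real genes of a list move together, so this overstates what camera can find in them.

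Alternatives covered background correction, normalization between arrays, the series matrix values, the filter on dim probes, a replicate block, trended and robust variances, array weights, leaving out each array, a fold threshold, the set test and the rule for several probes of a gene. Matrix values were floored at 0 and offset by 16 before log2. One alternative, the matrix values with each column given to the array of the same rank order, was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.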

Results

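The series asks which genes of the carotid endothelium respond to disturbed flow, the oscillating low-shear flow of curved or branched vessels, as against stable flow, and its title names thrombospondin-1 in arterial stiffening. The 6 arrays comprised 3 described as stable flow and 3 described as disturbed flow. The share of probes above background differed widely between arrays. It was 35.0%, 9.74% and 24.6% on stable flow replicates 1, 2 and 3, and 34.7%, 29.7% and 19.6% on disturbed flow replicates 1, 2 and 3. Pairwise correlations of normalized log2 intensity over probes ranged from 0.568 to 0.807, and stable flow replicate 2 took part in the 5 lowest.

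**Figure D1:**
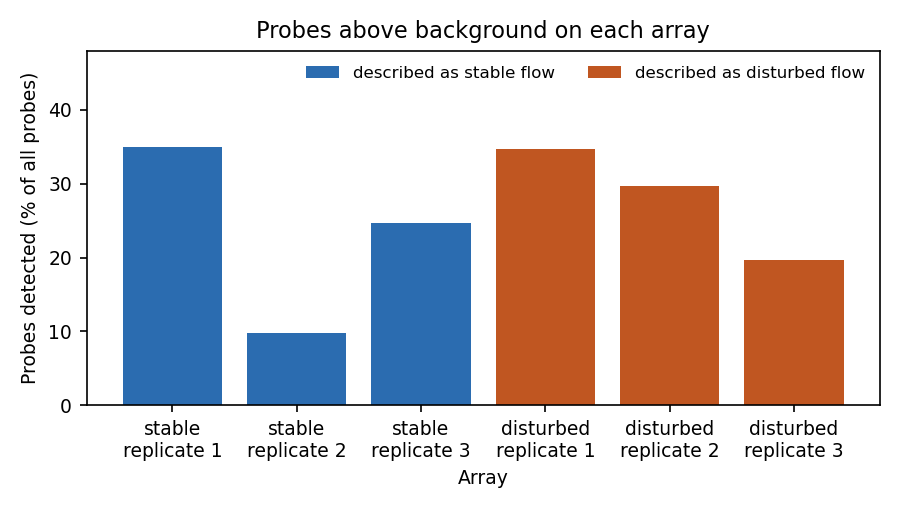
Share of the 45281 probes with a detection p under 0.05 on each array, in percent, coloured by the described group. Stable flow replicate 2 had 9.74% of probes above background, and the other arrays had 19.6% to 35.0%.

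Thrombospondin-1 and its pathway were not found to differ between the described groups. Thbs1 (probe ILMN_2659151), which encodes the matricellular glycoprotein thrombospondin-1, had a log2 intensity of 5.92 ± 1.56 on the arrays described as stable flow and 5.83 ± 1.57 on those described as disturbed flow (SD, n = 3 each). The difference was -0.09 (SE 0.99, limma adjusted p = 0.988), with the probe above background on 4 of 6 arrays. Its sign is the one given by the sample descriptions. The deposited matrix columns, which follow arrays of the other described group, turned the signs of all 38 genes named here, Thbs1 among them. The signs of list medians were not followed with those columns. The Thbs1 difference also turned to 0.74 without stable flow replicate 3, to 0.03 without disturbed flow replicate 2 and to 0.65 without disturbed flow replicate 3. The thrombospondin receptor Cd47 differed by 0.32 (SE 0.71) and turned to -0.46 without disturbed flow replicate 2. It gave 0.86 after scaling to a common 75th percentile and 0.77 with array weights, and its other probe gave 0.72 (SE 0.55). The scavenger receptor Cd36, also a thrombospondin receptor, differed by 0.01 (SE 0.32) and had -0.23 after scaling to a common 75th percentile, with the probe above background on 3 of 6 arrays.

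Of the 17 measured genes of thrombospondin-1, its receptors and the TGF-beta pathway, 0 passed the test over all probes and 0 when adjusted over the list alone, with a median difference of 0.32. That median ranged from 0.13 without stable flow replicate 1 to 0.47 without stable flow replicate 3. Acvrl1, an endothelial receptor of the TGF-beta family, had 5.00 ± 0.63 against 6.29 ± 0.50 (difference 1.29, SE 0.46, limma adjusted p = 0.890), and the difference was 0.70 with scaling to a common 75th percentile, 0.78 with cyclic loess and 0.45 with no background correction. Tgfbr2 differed by 1.76 (SE 1.02), by 0.62 without disturbed flow replicate 3 and by 0.75 with array weights, and its other probe gave -0.09. Among 10 collagens the median was 0.29, and -0.28 without stable flow replicate 2. Col3a1 stood at 2.11 (SE 0.90), with 1.27 without disturbed flow replicate 3, Col18a1 at 0.90 (SE 0.47), with 0.49 without disturbed flow replicate 2, and Col1a1 at -0.39 (SE 0.41), with -0.02 without stable flow replicate 1. The 6 matricellular genes had a median of 0.46, which ranged from 0.26 without stable flow replicate 2 to 0.73 without stable flow replicate 3, and held a pair of related growth regulators with opposite signs. Ccn1 had 7.34 ± 0.27 against 9.03 ± 1.25 (difference 1.69, SE 0.62, and 0.94 without disturbed flow replicate 2), with 2.52 and 0.02 for its other probes. Ccn2, also known as Ctgf and with -1.94 for its other probe, had 9.02 ± 1.00 against 7.48 ± 1.52 (difference -1.54, SE 0.83), with -2.39 without disturbed flow replicate 1 and -0.95 without disturbed flow replicate 3. The 14 genes of elastic fibres and collagen crosslinking had a median of -0.02, and of 0.065 without stable flow replicate 1. Eln, which encodes elastin, differed by 1.05 (SE 0.93), by 0.04 without stable flow replicate 2 and by 2.08 without stable flow replicate 1. The crosslinking enzyme gene Lox differed by 0.07 (SE 0.43), a value that turned to -0.11 without stable flow replicate 3 and to -0.27 without disturbed flow replicate 3. The 14 matrix proteases and inhibitors had a median of 0.26, which ranged from 0.046, with 7 higher and 7 lower values, without disturbed flow replicate 3 to 0.47 without disturbed flow replicate 1. Scaling to a common 75th percentile gave 0.47 for Col18a1 and -0.71 for Col1a1, cyclic loess gave 0.58 for Eln, whose other probe gave 0.83, and no background correction gave 0.91 for Col3a1. Col3a1 and Col1a1 were above background on 1 array described as stable flow and 2 described as disturbed flow, and Acvrl1, Tgfbr2, Col18a1 and Eln on 2 and 3. Among the stable flow arrays, Acvrl1, Tgfbr2, Col18a1 and Eln were lowest on replicate 2 (4.29, 4.98, 4.34 and 5.17), the array with the fewest probes above background. Without that array the Acvrl1 difference was 0.99. None of the genes of these lists passed the test over all probes or adjusted over the list alone.

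**Figure D2:**
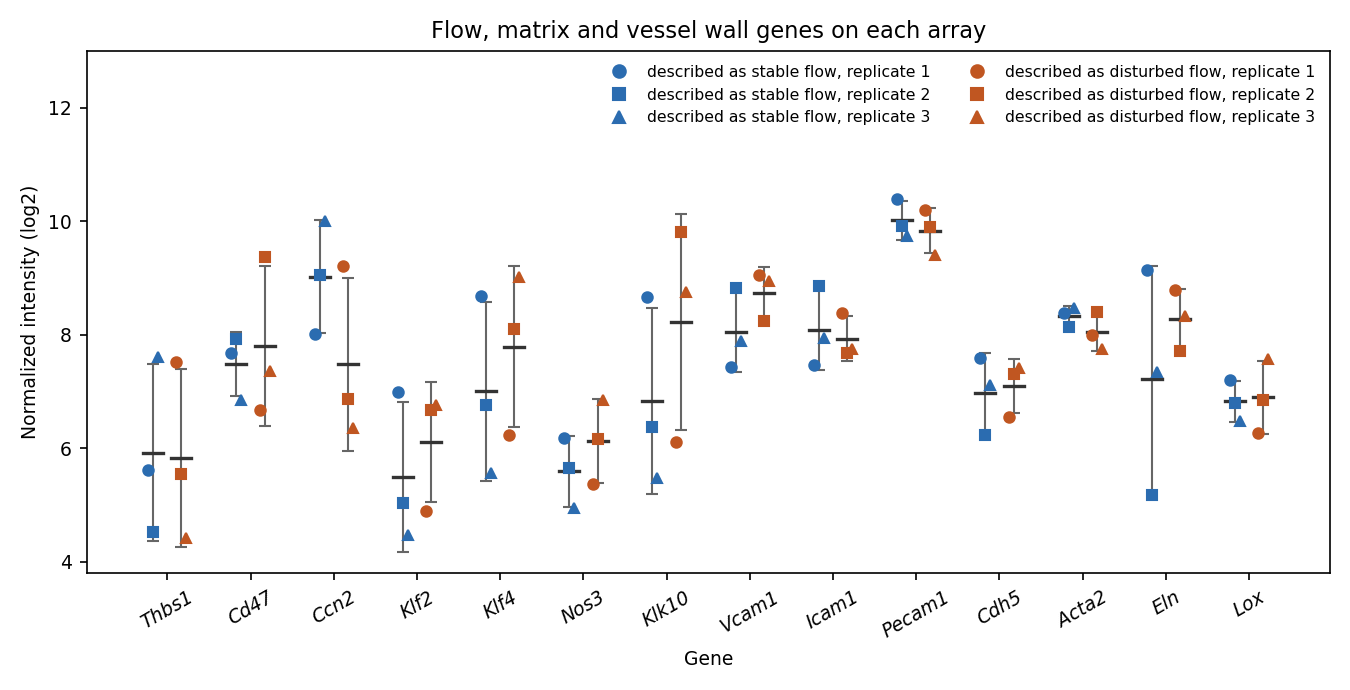
Normalized log2 intensity of 14 genes on each array, with the described groups side by side; points are arrays, horizontal bars are group means and whiskers are 1 SD (n = 3). The groups overlap for each of the 14 genes, and Thbs1 averages 5.92 and 5.83.

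On the probes that stand for them, shear-responsive Klf2, Klf4, Nos3 and Klk10 had SDs within both described groups larger than the differences between them. Klf2, a transcription factor induced by laminar shear, had 5.50 ± 1.32 on arrays described as stable flow and 6.11 ± 1.06 on those described as disturbed flow (difference 0.61, SE 0.78, limma adjusted p = 0.895). The related Klf4 differed by 0.78 (SE 0.95), the nitric oxide synthase gene Nos3 by 0.54 (SE 0.51), and Klk10 by 1.39 (SE 1.12). When single arrays were left out these values ranged from 0.09 to 1.22 for Klf2, 0.06 to 1.71 for Klf4, 0.19 to 0.87 for Nos3 and 0.58 to 2.42 for Klk10. Other probes gave 1.40 and 1.07 for Klf4 and 1.07, 0.84 and 0.58 for Nos3, and the first of these Nos3 probes had SDs of 0.98 and 0.78, smaller than its difference. Scaling to a common 75th percentile gave 0.12 for Klf2, 0.24 for Nos3 and 1.30 for Klf4. Klf2 was above background on 1 array described as stable flow and 3 described as disturbed flow, and Nos3 on 2 and 3. Over the 13 measured genes of the list raised by stable laminar flow the median was 0.61, with 11 higher and 2 lower values and 0 genes past the test over all probes or adjusted over the list alone. That median ranged from 0.16 without stable flow replicate 3 to 1.20 without stable flow replicate 1. Ptgis, the prostacyclin synthase gene, stood at 1.68 (SE 0.85), with 0.72 without stable flow replicate 2 and 1.06 with cyclic loess, and Gclm, of glutathione synthesis, at -0.67 (SE 0.36). Of 13 genes of endothelial inflammation and adhesion, 0 passed either adjustment, and the median was -0.11, with 0.018 without disturbed flow replicate 3. The leukocyte adhesion gene Vcam1 differed by 0.69 (SE 0.47), by 1.41 with scaling to a common 75th percentile and by 0.41 to 1.08 when single arrays were left out, and its other probes gave 0.10 and -0.04. The chemokine gene Cxcl1 differed by -0.78 (SE 0.45), with -0.41 without disturbed flow replicate 2, and Cxcl12 by 0.83 (SE 0.49), with 0.47 without disturbed flow replicate 1 and 1.06, 0.52 and -0.14 for its other probes. Scaling to a common 75th percentile gave -0.45 for Gclm and -0.17 for Cxcl1. Ptgis and Cxcl12 were above background on 2 arrays described as stable flow and 3 described as disturbed flow. Among the stable flow arrays both were lowest on replicate 2 (4.29 and 5.46), the array with the fewest probes above background. Icam1 differed by -0.15 (SE 0.46), turning to 0.39 with scaling to a common 75th percentile and to 0.24 without stable flow replicate 2.

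The list nearest to the threshold was that of interferon-stimulated genes, whose 10 measured members had a median of 0.51 (camera adjusted p = 0.466, and adjusted p = 0.959 with an estimated correlation). The median was 0.22 without disturbed flow replicate 1 and 0.34 without disturbed flow replicate 3. Its examples were Psmb9, an immunoproteasome subunit gene, at 6.33 ± 0.82 against 7.60 ± 0.20 (difference 1.27, SE 0.47, and 0.82 without stable flow replicate 2), and the guanylate-binding protein gene Gbp2 at 5.06 ± 0.66 against 6.53 ± 0.96 (difference 1.47, SE 0.58). With no background correction the differences were 0.63 and 0.56, cyclic loess gave 0.84 for Psmb9, and the other Gbp2 probe gave 1.04. Both genes were above background on 2 arrays described as stable flow and 3 described as disturbed flow. Among the stable flow arrays both were lowest on replicate 2 (5.41 and 4.37), the array with the fewest probes above background. Of the list's members, 0 passed over all probes and 0 adjusted over the list alone.

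Markers of the vessel wall cells were present in both described groups. The endothelial adhesion gene Pecam1 had 10.01 ± 0.34 and 9.83 ± 0.40, a difference of -0.18 (SE 0.37) that turned to 0.69 with scaling to a common 75th percentile, with -0.20 and 0.084 for its other probes. The endothelial cadherin gene Cdh5 differed by 0.11 (SE 0.47), and by -0.07 with cyclic loess, with 0.21 for its other probe. The smooth muscle actin gene Acta2 had 8.33 ± 0.17 and 8.05 ± 0.33, a difference of -0.29 (SE 0.34) that turned to 0.33 with scaling to a common 75th percentile, and its other probes gave 0.91, 0.38 and -0.12. The smooth muscle myosin gene Myh11 differed by 0.16 (SE 0.33), and by -0.06 with that scaling, with the probe above background on 3 of 6 arrays. When single arrays were left out, Acta2 ranged from -0.45 to -0.13 and Myh11 from 0.07 to 0.31. Median differences were 0.29 over 21 endothelial markers, 0.16 over 11 smooth muscle markers, 0.11 over 9 fibroblast and adventitia markers and 0.45 over 5 macrophage and monocyte markers. The median over all tested probes was 0.098, so list medians near that value do not set a list apart. The macrophage value rested on disturbed flow replicate 1, without which it was -0.33. Without stable flow replicate 2 the endothelial, smooth muscle and fibroblast medians were -0.08, -0.16 and -0.43. When single arrays were left out, the median turned sign for 16 of the 24 tested lists and moved by over 1.5 times for the other 8. Fewer than 5 genes were measured for lymphocyte, neutrophil, adipocyte, skeletal muscle, Schwann cell and nerve, red cell and platelet, thyroid and parathyroid, and X-inactivation and Y-linked genes. These were not tested as lists, and 0 of their members passed.

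Among the remaining lists, median differences were 0.18 for 10 YAP/TAZ targets, 0.16 for 12 genes of arterial identity and Notch signalling, and 0.03 for 11 genes of endothelial-to-mesenchymal transition. They were -0.06 for 11 cell cycle genes, 0.09 for 12 genes of oxidant production and defence, -0.07 for 16 genes of ER stress and the unfolded protein response, 0.49 for 14 genes of glycolysis and hypoxia, and 0.14 for 27 genes of oxidative phosphorylation. They were 0.02 for 8 genes of cholesterol synthesis, 0.38 for 8 immediate early genes, 0.08 for 28 ribosomal protein genes and -0.02 for 11 heat shock genes. All tested probes together had a median of 0.098. Of these lists, 3 kept their sign when single arrays were left out, with 0.11 to 0.37 for arterial identity, 0.22 to 0.85 for glycolysis and hypoxia, and 0.087 to 0.57 for immediate early genes. Camera compares a list with all other genes, and its direction was opposite to the median for the YAP/TAZ, oxidant, oxidative phosphorylation, fibroblast and heat shock lists, while the mean and the median differed in sign for the cell cycle, ER stress and heat shock lists.

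**Figure D3:**
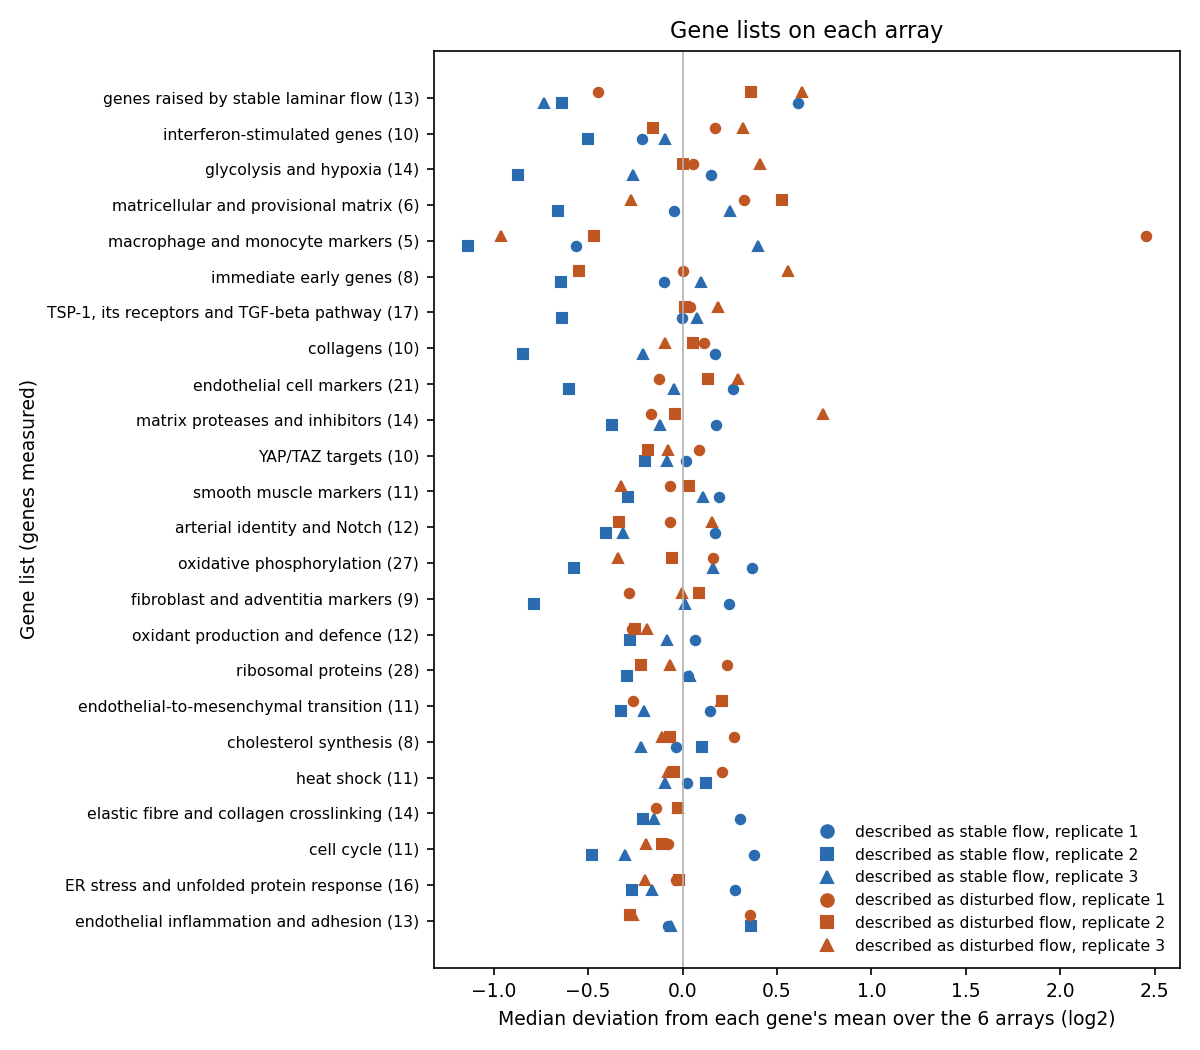
Median log2 deviation of each of the 24 tested lists on each array, relative to each gene's mean over the 6 arrays, with the number of genes measured in parentheses. The list raised by stable laminar flow ranged over 1.37 between arrays, and the macrophage and monocyte list over 3.59, with its highest value on disturbed flow replicate 1.

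The genes with the smallest p-values did not pass the adjustment either. Higher on the arrays described as disturbed flow were Actn1, the alpha-actinin-1 gene, by 3.54 (SE 0.66), the kinase gene Map2k4 by 3.60 (SE 0.85) and the monoglyceride lipase gene Mgll by 1.39 (SE 0.31). The Mgll probe was above background on only 1 array described as stable flow, so its difference rests on values near the floor there, and those of Actn1 and Map2k4 were on 2. Among the stable flow arrays, Actn1 and Map2k4 were lowest on replicate 2 (4.49 and 4.22). Without that array their differences were 2.92 and 2.85. Xlr4a and Malt1, a gene of NF-kappaB signalling, were above background on 0 arrays described as stable flow and on 3 described as disturbed flow. The filter on dim probes keeps a probe with 0 such arrays in 1 group only if all 3 of the other group are above background. The share of all tested probes with this pattern is not given here. Intensities of Xlr4a and Malt1 were at least 1.74-fold and at least 1.97-fold higher on the arrays described as disturbed flow. These bounds take for each dim array the larger of its own value and the lowest signal above background. Lower were Cops5, of the COP9 signalosome, by -1.43 (SE 0.30), Pkig by -1.63 (SE 0.37), the RNA helicase gene Ddx3x by -1.44 (SE 0.34), Ccdc47 by -1.54 (SE 0.37) and Tnrc6b by -1.51 (SE 0.39). The sizes of these 10 genes depended on the background correction: without it the log2 differences were 0.56 for Xlr4a, 0.58 for Malt1 and 0.42 for Mgll, and the bounds do not hold there. They were then 2.15 for Actn1, 2.22 for Map2k4, -0.57 for Cops5, -1.05 for Pkig, -0.95 for Ddx3x, -0.75 for Ccdc47 and -0.70 for Tnrc6b, and Ddx3x gave -0.89 with scaling to a common 75th percentile. Other probes did not bear out several of these values, with 0.76 for Mgll, -0.18 for Map2k4, -0.93 for Cops5, -1.32 and 0.0092 for Pkig, -0.33 for Ddx3x, 0.63 and 0.45 for Ccdc47 and 0.04 for Tnrc6b. Each of the 10 had a limma adjusted p of 0.890. Each also had groups that did not overlap, which the choice by smallest p favours.

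With no background correction 29 of the 38 genes named here moved by over 1.5 times. Over all 12546 probes, limma called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.890. At an unadjusted p under 0.05 there were 338 probes, 194 higher and 144 lower, where 627 would be expected by chance. The described groups did not overlap for 1215 probes, or 9.68%, against 10% by chance for 3 against 3. Of the 24 lists, camera called 0, camera with an estimated correlation 0 and fry 0. Scaling to a common 75th percentile gave 5 camera calls and no normalization gave 2, of which 0 remained with an estimated correlation (smallest adjusted p = 0.404 and 0.959). Slide and described group cannot be told apart, and log2 changes of 2 were recovered in only 26.1% of simulated cases, so changes of that size can be missed.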

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

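The added alternative, the matrix columns given to arrays of the same rank order, was chosen after the data were seen. For the counts of probes and lists it is the same test as the matrix columns as named, with the groups exchanged. The fold threshold could only repeat a count of 0 probes. The number of probes called by limma was 0 under all 19 alternatives, with 15 (no normalization) to 2097 (no filter, 45281 probes) at an unadjusted p under 0.05. Without stable flow replicate 2, the array with the fewest probes above background, 386 were, and 0 lists were called. The number of lists called was 0 in 19 of 21 alternatives, 5 with scaling to a common 75th percentile (laminar flow, arterial identity, ribosomal, heat shock and endothelial lists, all higher) and 2 with no normalization (laminar flow and ribosomal lists); the cause was not tested. With an estimated correlation 0 lists were called under either setting (smallest adjusted p = 0.404 and 0.959). These scalings moved the median of all probes from 0.10 to -0.08 and -0.10. Thbs1 ranged from -0.90 to 0.74 when single arrays were left out, and its adjusted p was 0.853 to 1 over 18 alternatives. It had no value with detection on all 6 arrays required, and as a gene with 1 probe it could not move under the mean over probes. The slide block was not run, since each slide holds 1 group. With the replicate block 0 probes were called, with 329 at an unadjusted p under 0.05. Thbs1 stayed at -0.09, since a block that holds 1 array of either group cannot change a group difference. Deviations of same-numbered samples correlated at -0.03, -0.07 and -0.08, and no stable flow sample correlated best with its own number. These values do not show a pairing by number. They cannot exclude one either, since the arrays differ widely in the share of probes above background. Weak signal limits the dim arrays: 2500 probes were above background on all 6.

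Of the 113 probes that the naming rule takes, 0 were called under any alternative. Signs turned for 113 of 113 with the matrix columns as named, which the construction of that alternative explains, since its columns exchange the groups. They turned for 22 with no normalization, 21 with scaling to a common 75th percentile, 11 with array weights, 9 with cyclic loess, 1 with no background correction and 2 to 14 when an array was left out. With the matrix columns as named the log2 differences were 0.13 for Thbs1, -0.32 for Cd47, -0.0090 for Cd36, 0.39 for Col1a1, -1.05 for Eln, -0.073 for Lox, -0.65 for Klf2, -0.78 for Klf4, -0.54 for Nos3, -1.38 for Klk10, -0.69 for Vcam1, 0.15 for Icam1, 0.18 for Pecam1, -0.11 for Cdh5, 0.28 for Acta2 and -0.25 for Myh11. They were -3.55 for Actn1, -1.89 for Xlr4a, -1.58 for Mgll, -2.07 for Malt1, -3.66 for Map2k4, 1.41 for Cops5, 1.62 for Pkig, 1.43 for Ddx3x, 1.53 for Ccdc47 and 1.49 for Tnrc6b. They were -1.39 for Acvrl1, -1.75 for Tgfbr2, -2.23 for Col3a1, -1.003 for Col18a1, -1.68 for Ccn1, 1.53 for Ccn2, -1.78 for Ptgis, 0.66 for Gclm, 0.78 for Cxcl1, -0.82 for Cxcl12, -1.26 for Psmb9 and -1.55 for Gbp2. Of the genes named in the text, the other turned signs were those of differences smaller than their SE, and the cause was not tested. Of these 38 genes, 29 moved by over 1.5 times with no background correction (median size 0.475 of the reported one), 22 with normexp on the signal alone (0.622), and 25 moved so or turned when an array was left out. Scaling to a common 75th percentile gave -0.23 for Cd36, 0.39 for Icam1, 0.69 for Pecam1, 0.33 for Acta2 and -0.059 for Myh11. No normalization gave -0.25 for Cd36, 0.37 for Icam1, 0.67 for Pecam1, 0.31 for Acta2 and -0.081 for Myh11. Cyclic loess gave -0.036 for Cd36 and -0.075 for Cdh5, and array weights gave -0.14 for Cd36, 0.10 for Icam1 and -0.16 for Cdh5. When single arrays were left out, the range was -0.10 to 0.11 for Cd36, -0.50 to 0.24 for Icam1, -0.36 to 0.035 for Pecam1, -0.27 to 0.44 for Cdh5, -0.27 to 0.37 for Lox and -0.46 to 0.89 for Cd47.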

Other observations

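The counts for the described groups and the camera test of the laminar flow list between them were planned, and the other tests in this part were chosen after the values of the single arrays had been seen. Of 22 macrophage and monocyte markers named on the array, 5 passed the filter, and 4 of these were highest on disturbed flow replicate 1. A marker above background on that array alone could not have passed. Lyz2, a lysozyme gene of myeloid cells, had a log2 intensity of 8.01 on disturbed flow replicate 1 and 4.35 to 5.91 on the other arrays. Lyz1 had 8.34 there against 4.75 to 6.54, and Tyrobp, an adaptor of myeloid receptors, 8.09 against 4.40 to 5.99. Laptm5, of leukocyte lysosomes, had 7.04 against 4.28 to 6.23, while the protease gene Lgmn did not stand apart, with 5.76 against 4.27 to 5.86. Lyz1, Lyz2 and Tyrobp were above background on 4 of the 6 arrays, so their ranges include values that were not above background. Lyz1, Tyrobp, Laptm5 and Lgmn were chosen after their values were seen.

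With no probe called between the described groups, the 10 ways to split the 6 arrays into 3 and 3 were compared. The described split had 338 probes at an unadjusted p under 0.05. Counting the described split itself, 6 of the 10 splits had at least as many, and the highest of the others had 653. Camera called 0 lists in the described split and 3 in the highest of the others; all 10 splits reach a count of 0, so this gives no test. These 10 splits are too few for a share under 0.05.

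Genes raised by laminar flow varied between arrays within both described groups, as Klk10 did with 8.66, 6.37 and 5.47 on stable flow replicates 1, 2 and 3, and 6.11, 9.80 and 8.75 on disturbed flow replicates 1, 2 and 3. Klk10 ranged over 4.33, while the 13 genes had ranges from 0.99 for Aqp1 to 4.54 for Srxn1. Not all followed its pattern, and Txnip was highest, at 9.50, on disturbed flow replicate 1. Noise or weak signal of single arrays is neither shown nor excluded. The list's range over the arrays, 1.37, lay at percentile 94.96 of 10000 random lists matched on mean intensity, too near its bound to decide. Members of the random lists were drawn gene by gene, while the laminar flow genes vary together (estimated correlation 0.31). The percentile could therefore not decide even away from its bound. The bound and the margin around it were set after values had been seen, and without the margin this test would have gone with noise. This was the third form of the test, chosen after the first and the second had come out against noise, though neither can bear on it: the first set disturbed flow replicate 3 against replicate 1 (mean difference 0.73 over 13 genes, which vary together and are no replicates), and the second compared sets of arrays drawn from the values. A different share of endothelial RNA on each array is not excluded either. The range was 1.06, percentile 83.3, once each array's endothelial marker median was subtracted. Its random lists were also drawn gene by gene, so this percentile has the same limit. This test replaced one between sets of arrays that had come out against this explanation. The replaced test was void because its sets were drawn from the values. Whether single arrays carry the label of the other group stays open, since the split with the largest median difference of the list (-1.32, against an absolute 0.67 for the next) was noticed from the same genes; biological differences between samples were not tested.

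That split sets stable flow replicate 1 and disturbed flow replicates 2 and 3 apart from the rest, and is the one that called 3 lists, those of laminar flow (adjusted p = 0.000107), inflammation (adjusted p = 0.0222) and macrophages (adjusted p = 0.00704), of which 0 remained with an estimated correlation or with fry. It also follows the numbers in the sample titles, 7, 9 and 8 against 10, 12 and 11. These values stand as part of the listing of all 10 splits and test nothing, because sets drawn from measured values cannot test what they were drawn from; further tests of the laminar flow list between these sets were left out for that reason. The split called 0 probes, with 599 at an unadjusted p under 0.05. The title numbers can also be read as consecutive pairs, 7 and 8, 9 and 10, and 11 and 12. Each such pair holds 1 array of either described group. The replicate block paired the arrays otherwise, and a pairing by title number was not tested.

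The matrix columns follow arrays of the other described group, so the groups may have been exchanged as a whole in 1 of the sources. The laminar flow list had a median of 0.61 on the arrays described as disturbed flow minus those described as stable flow, and limma's camera gave an adjusted p of 0.718. Camera called the list higher with scaling to a common 75th percentile (adjusted p = 1.79e-05) and with no normalization (adjusted p = 0.000204), calls that were lost with an estimated correlation (smallest adjusted p of any list 0.404 and 0.959). The median of the laminar flow list ranged from 0.16 to 1.20 when single arrays were left out, higher each time on the arrays described as disturbed flow. Since camera did not call the list in the planned test, the exchange is neither shown nor excluded.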
